A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

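Total RNA from 14 Saccharomyces cerevisiae cultures grown in rich YPD medium to log phase was hybridised to Affymetrix Yeast Genome 2.0 arrays, 1 array per culture. The labels give deletions of NPT1, PNC1, BNA1 and TNA1, a wild type with 5 mM nicotinamide, and wild-type arrays in pairs coded ML1 and ML8. Each of these 7 groups holds 2 arrays, which the series describes as duplicate cultures. The wild-type genotype is MATa with auxotrophic marker alleles, and the labels give no hybridisation batch.

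The deposited table holds log2 signal values for 10928 probe sets on all 14 arrays, which the authors computed with GCRMA, a background correction, quantile normalization and summary of the probes of a set. The GCRMA version is not given in the sources used here. The values were used as deposited, and depth does not apply to arrays, whose number limits the precision.

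Probe sets were paired with genes through the annotation supplied with the series and named from the S. cerevisiae reference assembly R64, which served only for names and for the order of genes. Of the probe sets, 5498 matched 1 S. cerevisiae gene each, together 5449 genes. A further 1746 had an annotated gene that is not in that reference, 1 had several genes, 213 were array controls and 3470 had no gene given. Of the 5498 tested probe sets, 128 are of a design shared between near-identical genes. For a gene with several probe sets, the one with the highest mean signal stood for the gene. The 95th percentile of the 1746 probe sets without a gene in the reference gave the background limit of each array, between 2.22 and 2.26 on the log2 scale. A fold change against a group with every array below this limit was computed against the limit and is written as a lower bound.

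Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 14 arrays. The 4 wild-type arrays formed a single group, since the labels do not say which pair belongs to which condition. The fit left 8 residual degrees of freedom, and the moderation added 2.01 with a prior SD of 0.101 (log2). P values were adjusted within each comparison by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05, with no minimum fold and no filter on dim probe sets. The ML1 and ML8 pairs were compared in a fit of all 7 groups. The 5 main comparisons set each condition against wild type, and 4 more set conditions against each other.

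There were 24 gene lists, written from textbook knowledge: the deleted genes, de novo NAD+ synthesis, NAD+ salvage and vitamin uptake, thiamine synthesis and uptake, middle sporulation, sirtuins and their partners, the silent mating loci, alpha-specific, a-specific and haploid-specific genes, seripauperin (PAU) genes, the DNA damage response, tryptophan synthesis, general amino acid control, sulphur and methionine, purine synthesis, phosphate starvation, the iron regulon, genes raised in the environmental stress response, ribosomal proteins, ribosome biogenesis, the respiratory chain, hexose transporters and core histones. Lists with at least 4 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Genes among the 10 outermost protein-coding genes of each chromosome end were tested in the same way as a separate set, with p adjusted over the 5 comparisons against wild type. Apart from that adjustment and the later additions, the comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined.

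By that rule, the text names for each main comparison up to 8 of the largest rises and 8 of the largest falls among called genes whose arrays of that condition lie outside the range of the 4 wild-type arrays. It also names the deleted genes, up to 4 called members of each list with the largest change, 2 members with the highest signal where none passed, genes called in at least 3 conditions, and neighbours of a deleted gene. Other genes are named as chosen after their values were seen.

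The scripted steps were tested on simulated data with 5498 genes, of which 200 were changed, in 20 simulations. For the npt1 comparison, 34.1% of 1.25-fold, 67.7% of 1.5-fold, 88.9% of 2-fold and 97.4% of 4-fold changes were recovered, and 5.39% of the calls were false. For the bna1 comparison the shares were 31.9%, 68.6%, 90.5% and 98.2%, with 5.77% of the calls false. A list of 15 genes without a shift was called in 1 of 20 simulations by camera and in 1 by fry, and a shift of 0.2 (log2) was called in 20 of 20 by both.

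The alternatives were the control pair (only ML1 or only ML8), the wild-type pairs as separate groups, the replicate letter as a block, a fit of only the groups compared, quantile normalization of the deposited values, centring on the array median, a filter on dim probe sets, a variance trend, robust or no moderation of variances, all probe sets in the fit, a 2-fold minimum, and leaving out each array in turn. After the data were seen, the comparison of nicotinamide with the npt1 deletion, lists without the deleted gene, genes by rank from the chromosome end, lists between the wild-type pairs (24 sets, adjusted together), probe sets with no gene given, simulations in which the called changes of each condition sit at random genes and the wild-type arrays are shared, and the adjustment over comparisons for genes near chromosome ends were added. Splits of the samples were not tested, because every condition has only 2 arrays. Raw probe intensities were not used here.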

Results

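Transcript levels were measured on 14 arrays, with 2 cultures each of npt1Δ, pnc1Δ, bna1Δ, tna1Δ, wild type with 5 mM nicotinamide, and the wild-type pairs ML1 and ML8. NPT1 and PNC1 act in the salvage of nicotinic acid and nicotinamide to NAD+, BNA1 in de novo synthesis from tryptophan, and TNA1 takes up nicotinic acid. The question in each comparison was how the genome-wide expression of cells with a changed NAD+ route or with nicotinamide, a product inhibitor of sirtuin deacetylases, differed from that of wild type. Median signal per array lay between 9.75 and 9.84 (log2), and 97.5 to 98.5% of the S. cerevisiae probe sets exceeded the background limit. Replicate arrays correlated at 0.9923 (ML1) to 0.9979 (pnc1Δ) across probe sets, and the median difference between 3' and 5' control probe sets was 2.29 to 2.52 per array. Array A of the ML1 pair differed by more than 1 (log2) from the mean of the other 3 wild-type arrays in 161 probe sets, against 12, 74 and 13 for the others. In 9 of 160 named probe sets, among them NPT1, CCM1, NRT1, BNA5, SPR3 and HXK1, a single wild-type array stood apart from the other 3, where chance gives about 8. Errors below are standard errors of the limma contrast, with 2 arrays per condition against 4 wild-type arrays.

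Each deleted gene was lost in its own strain. NPT1 was at least 1140-fold lower in npt1Δ, PNC1 at least 844-fold lower in pnc1Δ and BNA1 at least 166-fold lower in bna1Δ, with both mutant arrays below background. TNA1 fell by 10.31 ± 0.10 (log2) in tna1Δ, where 1 of 2 arrays lay just above the limit. Measured neighbours of the deleted genes did not pass the test, with log2 differences of -0.08 for PTP2 and 0.11 for RPB10 beside NPT1, -0.04 for OCH1 beside PNC1, 0.06 for MDE1 beside BNA1, and 0.02 for RAD2 and 0.00 for APL6 beside TNA1.

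Cells without NPT1, the nicotinate phosphoribosyltransferase of the salvage route, raised genes of NAD+ synthesis, thiamine metabolism and spore formation. The highest rises were those of CDA1, a chitin deacetylase of the spore wall (6.41 ± 0.10 log2, 85.1-fold, adjusted p = 1.3e-11), and BNA2, the first enzyme from tryptophan to NAD+ (6.02 ± 0.13, 65.1-fold, adjusted p = 3.09e-10). YMR244W rose at least 50.0-fold, YFL012W by 5.54 (log2), the spore gene LDS2 at least 27.8-fold, the a-factor receptor gene STE3 by 4.85 ± 0.21, the meiotic monopolin gene MAM1 by 4.84 and the allantoinase gene DAL1 at least 21.2-fold. Apart from NPT1 the falls were small, with TIR2, a cell wall mannoprotein gene, at -1.13 ± 0.08, YGP1 at -0.93, the glutathione transferase gene GTT1 at -0.91, the ferric reductase gene FRE3 at -0.85, CLD1 at -0.82, RPR2 at -0.71 and CCM1 at -0.65. In all, 231 of 5498 probe sets were called, 196 higher and 35 lower, of which 110 rose and 2 fell at least 2-fold. Fitted on the arrays of npt1Δ and wild type alone, 138 were called, and after quantile normalization of the deposited values 181 were higher and 117 lower.

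De novo NAD+ synthesis rose as a list in npt1Δ (camera, adjusted p = 2.83e-15), with 5 of 7 genes called higher and 6 when adjusted over the list alone. BNA1 rose by 3.24 ± 0.15 (log2), BNA4 by 2.82 and BNA5 by 1.91. In NAD+ salvage and vitamin uptake, 4 of 17 genes were higher and 1 lower (6 and 1 adjusted over the list alone), with TNA1 at 1.96 ± 0.10, the nicotinamide riboside transporter gene NRT1 at 1.98 and POF1 at 0.49. PNC1 had a log2 difference of 0.21 (adjusted p = 0.559). The salvage list's mean was -0.29 because it holds NPT1 itself, while its median was 0.10 and camera placed it up (adjusted p = 0.0244). That call was lost with an estimated correlation (adjusted p = 0.312) and against ML1 alone (adjusted p = 0.112), and fry gave the opposite direction (adjusted p = 2.52e-06). Without NPT1 the mean was 0.33 and camera again placed the list up (adjusted p = 0.000295, and adjusted p = 0.0933 with an estimated correlation).

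Middle sporulation genes, which wild-type cells in rich medium keep low, rose in npt1Δ, with 19 of 37 called higher, none lower, and 22 adjusted over the list alone (camera, adjusted p = 2.26e-25). MIP6 rose by 4.22, YSW1 by 4.15 and the septin gene SPR3 by 3.98 (log2). In thiamine synthesis and uptake, 6 of 18 were higher (7 adjusted over the list alone, adjusted p = 8.06e-06), with THI13 at 2.10 (a shared probe set), THI73 at 1.63, THI4 at 1.48 and the activator gene THI2 at 1.36. Of 13 PAU genes, 5 rose (7 adjusted over the list alone, adjusted p = 1.52e-08), with PAU21 at 1.36, PAU3 at 1.19, PAU8 at 0.98 and PAU14 at 0.89, all on shared probe sets. These lists kept their call with an estimated correlation.

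Smaller list shifts in npt1Δ rested on fewer genes and were lost with an estimated correlation. Of 4 alpha-specific genes, STE3 alone was called (2 adjusted over the list alone, adjusted p = 0.00454, and adjusted p = 0.054 with an estimated correlation). In the DNA damage response 2 of 14 rose, HUG1 by 1.36 and MAG1 by 0.84 (3 adjusted over the list alone, adjusted p = 0.0316, adjusted p = 0.357 with an estimated correlation, and adjusted p = 0.112 against ML1 alone). In phosphate starvation 2 of 16 rose, the phosphate transporter gene PHO89 by 2.51 and PHM6 by 2.38 (3 adjusted over the list alone, adjusted p = 0.0238, adjusted p = 0.0845 with an estimated correlation, and adjusted p = 0.0819 against ML8 alone). The respiratory chain was placed up with 1 of 29 genes called, CYC1 at 0.61, and 1 adjusted over the list alone (adjusted p = 0.000689, and adjusted p = 0.422 with an estimated correlation). Ribosome biogenesis was placed down with a mean of -0.14 and 0 of 22 called by either count (adjusted p = 0.00331, and adjusted p = 0.422 with an estimated correlation). Apart from BNA1, TNA1 and NPT1, called members of lists without a shift were the siderophore-binding mannoprotein gene FIT1 (3.11), the serine synthesis gene SER3 (0.77), MTD1 (0.59), the S-adenosylmethionine permease gene SAM3 (0.52), the lysine synthesis gene LYS1 (0.29), FRE3 (-0.85) and YGP1 (-0.93). The lists without a shift in npt1Δ were the deleted genes, sirtuins, a-specific and haploid-specific genes, tryptophan synthesis, general amino acid control, sulphur and methionine, purine synthesis, iron regulon, environmental stress, ribosomal proteins, hexose transporters and core histones (adjusted p from 0.071 to 0.982). Among their abundant members, STE2 differed by -0.02, MFA2 by 0.12, NET1 by -0.14, RPS15 by 0.02 and HTA2 by 0.04 (log2).

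**Figure D1:**
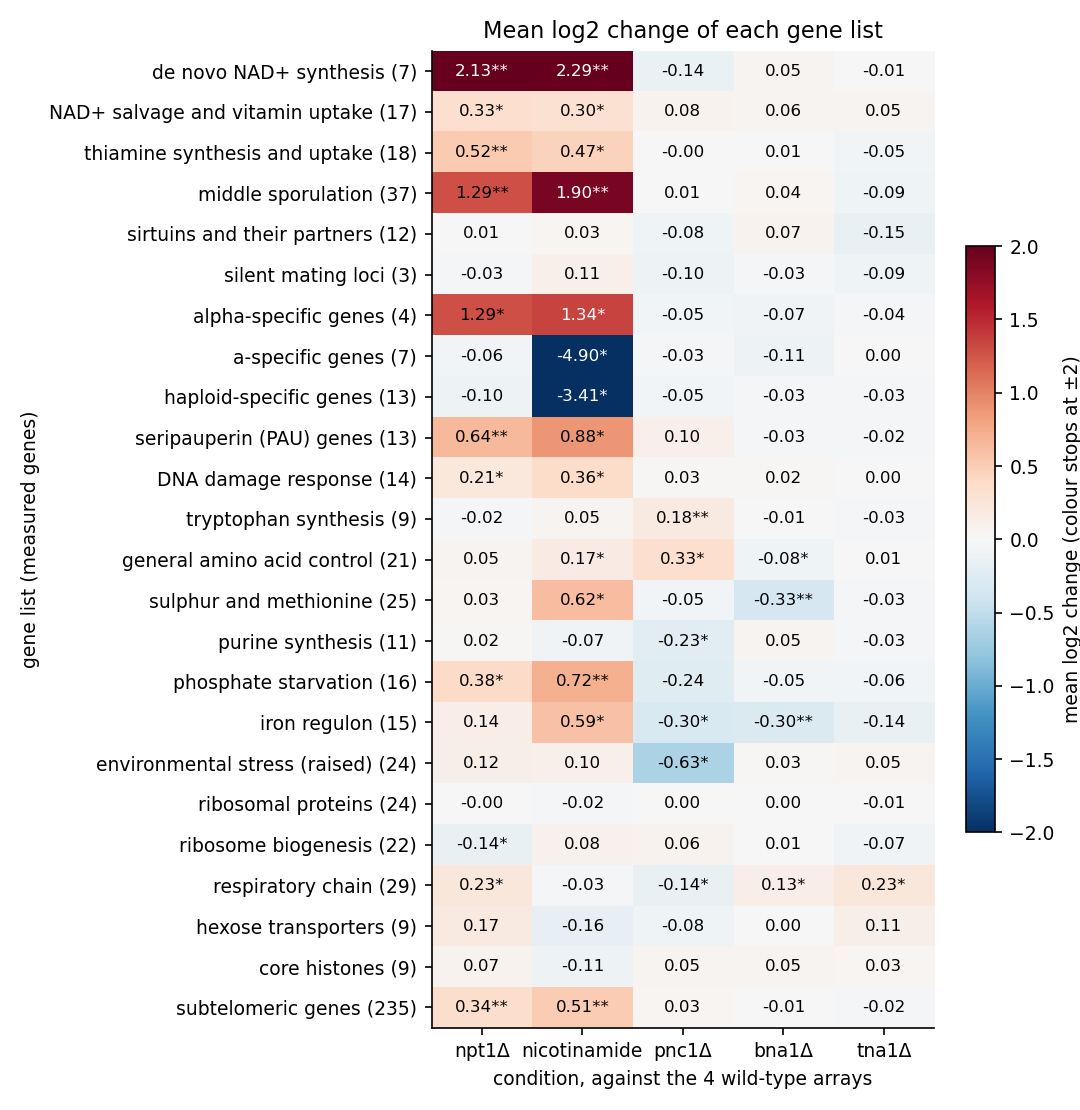
Mean log2 change of each gene list (rows, with the number of measured genes) in each condition against the 4 wild-type arrays (columns), leaving out a gene deleted in that strain. A star marks an adjusted p under 0.05 by camera on the whole list and a double star one that also holds with an estimated correlation; de novo NAD+ synthesis averaged 2.13 in npt1Δ and 2.29 in nicotinamide, and haploid-specific genes averaged -3.41 in nicotinamide.

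Nicotinamide at 5 mM raised de novo NAD+ and middle sporulation genes, and lowered genes that define the mating type and the haploid state. CDA1 rose by 6.75 ± 0.10 (log2, 108-fold, adjusted p = 7.48e-12), YFL012W by 6.20, BNA2 by 5.97 ± 0.13, MAM1 by 5.77, SPR3 by 5.42 and SPR2 by 5.40, while YMR244W rose at least 43.5-fold and the spore membrane gene SMA1 at least 34.7-fold. The largest falls were those of FAR1, which arrests the cell cycle in pheromone (-5.64 ± 0.63, 49.7-fold, adjusted p = 0.00011), and MFA1, which encodes a-factor (-5.63 ± 0.45, 49.6-fold, adjusted p = 8.52e-06). The agglutinin subunit gene AGA2 was at -5.43, ASG7 at -5.37, the pheromone kinase gene FUS3 at -5.34, the alpha-factor protease gene BAR1 at -5.06, and the a-factor exporter gene STE6 and the G protein gene GPA1 at -4.47 each. In all, 874 of 5498 probe sets were called, 488 higher and 386 lower, with 185 and 65 at least 2-fold. Without nicotinamide array B 458 were called, and 533 when only the nicotinamide and wild-type arrays were fitted. After quantile normalization of the deposited values the balance turned, with 455 called higher and 568 lower.

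All 7 a-specific genes and all 13 haploid-specific genes fell in nicotinamide, with mean log2 changes of -4.90 and -3.41, and the same numbers adjusted over the list alone. Camera gave adjusted p = 9.64e-10 and 2.74e-18 for these lists, and adjusted p = 0.0777 and 0.0574 with an estimated correlation. HO, the mating-type switching endonuclease gene, fell by 3.84. The fall averaged -3.07 on nicotinamide array A and -4.79 on array B, and each of the 20 genes was lower on array B. STE3 was the called member among 4 alpha-specific genes (5.06 ± 0.21, 1 adjusted over the list alone), a list placed up at adjusted p = 0.0286 and at adjusted p = 0.0847 with an estimated correlation. Of the silent mating loci, HMRA1 differed by 0.12 and HMRA2 by 0.20 (log2, a shared probe set), neither called. HMLALPHA1, also on a shared probe set, was below background on every array. MATa cells carry the a genes at MAT as well, so the HMRA1 and HMRA2 values cannot show whether HMR stayed silent.

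**Figure D2:**
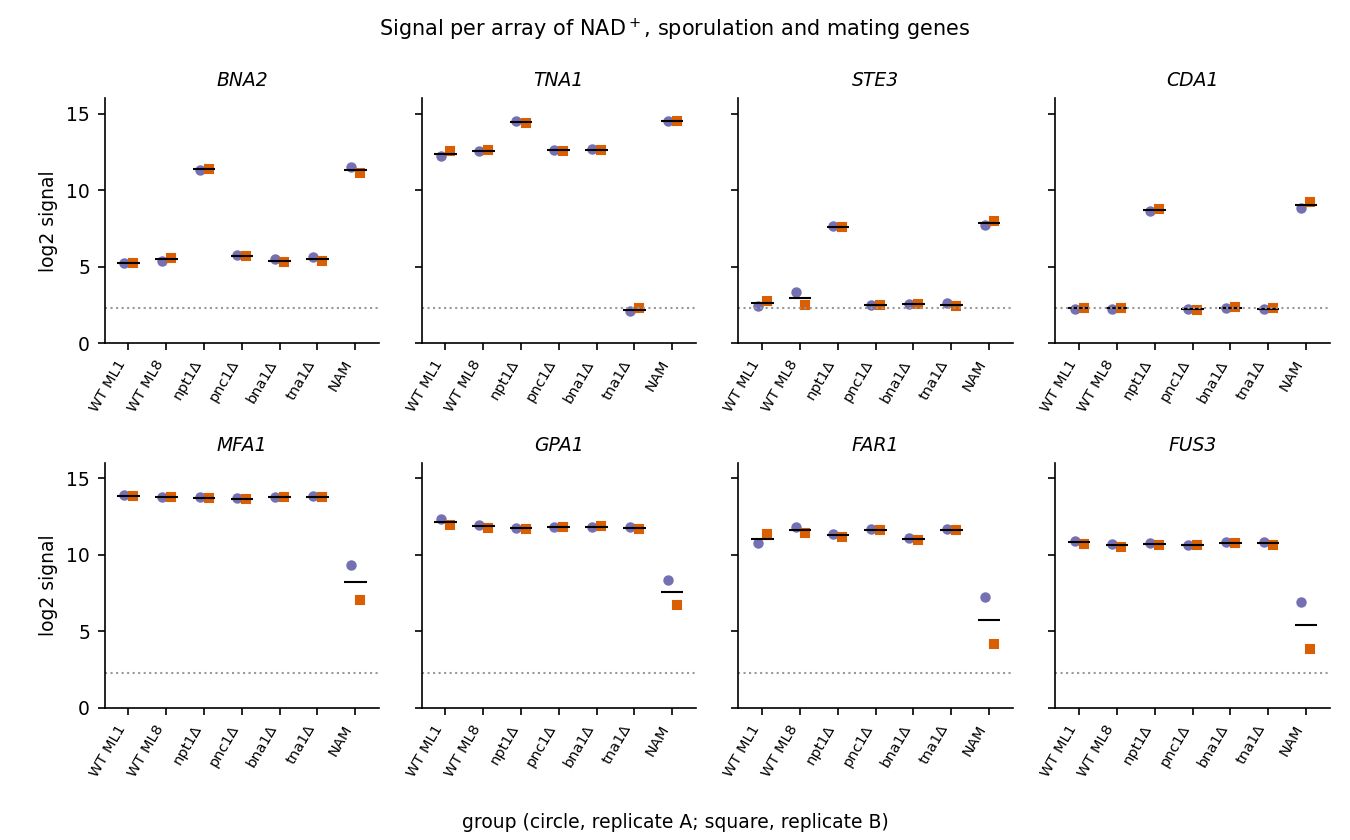
Log2 signal of 8 genes on each of the 14 arrays, by group, with circles for replicate A, squares for replicate B, a bar for the mean of the pair, and a dotted line at the highest background limit of any array, 2.26. MFA1, GPA1, FAR1 and FUS3 are lower on both nicotinamide arrays than on all other arrays, and BNA2, STE3 and CDA1 are higher on the npt1Δ and nicotinamide arrays than on all others.

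De novo NAD+ synthesis rose in nicotinamide in 6 of 7 genes (7 adjusted over the list alone, adjusted p = 3e-11), with BNA4 at 3.19, BNA1 at 3.07 ± 0.15 and BNA5 at 2.23 (log2). Middle sporulation rose in 29 of 37 genes (31 adjusted over the list alone, adjusted p = 2.92e-26), with MIP6 at 4.91 and YSW1 at 4.49. Phosphate starvation rose in 5 of 16 (9 adjusted over the list alone, adjusted p = 1.43e-05), with PHO89 at 3.03, PHM6 at 2.72, PHO11 at 0.62 (a shared probe set) and VTC3 at 0.61. These 3 lists held with an estimated correlation. In NAD+ salvage and vitamin uptake, 4 of 17 rose and 1 fell, with NRT1 at 2.10, TNA1 at 2.02 ± 0.10, FUN26 at 0.45 and POF1 at 0.44 (5 and 2 adjusted over the list alone, adjusted p = 0.0158, and adjusted p = 0.144 with an estimated correlation). PNC1, the nicotinamidase gene, differed by -0.49 ± 0.16 (adjusted p = 0.0752). In the list of the 4 deleted genes 2 were higher, BNA1 and TNA1 (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0221, and adjusted p = 0.0777 with an estimated correlation). Thiamine genes rose in 6 of 18 and fell in 2 (the same counts adjusted over the list alone, adjusted p = 0.0134, and adjusted p = 0.0574 with an estimated correlation), with THI13 at 3.08, THI73 at 1.98, THI4 at 1.89 and THI2 at 1.48.

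A further 5 lists were placed up in nicotinamide and lost their call with an estimated correlation. Sulphur and methionine genes were higher in 14 of 25 (19 adjusted over the list alone, adjusted p = 2.64e-09, and adjusted p = 0.0563 with an estimated correlation), among them ATP sulphurylase MET3 at 1.27, MUP3 at 1.11, SAM3 at 1.10 and MET14 at 1.05 (log2). The iron regulon was higher in 9 of 15 and lower in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.000213, and adjusted p = 0.0563 with an estimated correlation), with FIT1 at 3.62, the metal transporter gene FET4 at 1.73, FRE1 at 0.76 and ARN2 at 0.64. PAU genes rose in 7 of 13 (9 adjusted over the list alone, adjusted p = 7.51e-06, and adjusted p = 0.0634 with an estimated correlation), with PAU21 at 2.50, PAU3 at 1.93, PAU8 at 1.43 and PAU14 at 1.21. DNA damage response genes rose in 5 of 14 and fell in 1, with HUG1 at 2.45, MAG1 at 1.18, the ribonucleotide reductase gene RNR3 at 0.69 and DDR48 at -1.37 (6 and 1 adjusted over the list alone, adjusted p = 0.009, and adjusted p = 0.144 with an estimated correlation). General amino acid control had 3 of 21 called, ARG1 at 1.02, SER3 at 0.49 and LYS1 at 0.24 (4 adjusted over the list alone, adjusted p = 0.0331, adjusted p = 0.471 with an estimated correlation, and adjusted p = 0.125 against ML1 alone). Lists without a shift were sirtuins, tryptophan synthesis, purine synthesis, environmental stress, ribosomal proteins, ribosome biogenesis, the respiratory chain, hexose transporters and core histones (adjusted p from 0.086 to 0.936). Their called members were HSP12 (1.14), TSL1 (0.96), YGP1 (0.79), GRE3 (-0.24), COR1 (-0.30), the hexose transporter gene HXT4 (-1.19) and the histone gene HTA1 (-0.20).

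Of the 196 genes called higher in npt1Δ, 165 were also called higher in nicotinamide, where simulated changes at random genes, with the wild-type arrays shared, had 16.8 in common on average and 28 at most, and 188 (95.9%) had a positive change there. The simulations gave 52.3% on average and 60.6% at most. The same genes had a positive change in 60.2% of cases in bna1Δ, 52% in pnc1Δ and 44.9% in tna1Δ, where the simulations gave at most 59.5%, 59.6% and 58.8%. Of the 35 genes lower in npt1Δ, 31 had a negative change in pnc1Δ (88.6%, at most 77.8% in simulations), 30 in tna1Δ (85.7%, at most 75.9%), 29 in nicotinamide (82.9%, at most 78.1%) and 22 in bna1Δ (62.9%, at most 78.6%). The simulations gave a gene the same spread on every array and left out wild-type arrays that stand apart, such as ML1 array A. The shares for the 35 genes may therefore come from the shared wild-type arrays, and do not by themselves show a likeness between conditions. Of 35 lower in npt1Δ, 13 were lower in nicotinamide (2.69 on average in these simulations and 7 at most). Across genes, which are not independent replicates, the changes in npt1Δ and nicotinamide correlated at 0.635, against 0.338 in simulations in which only the shared wild-type arrays link them, and at 0.459 or 0.598 when each condition had its own wild-type pair.

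**Figure D3:**
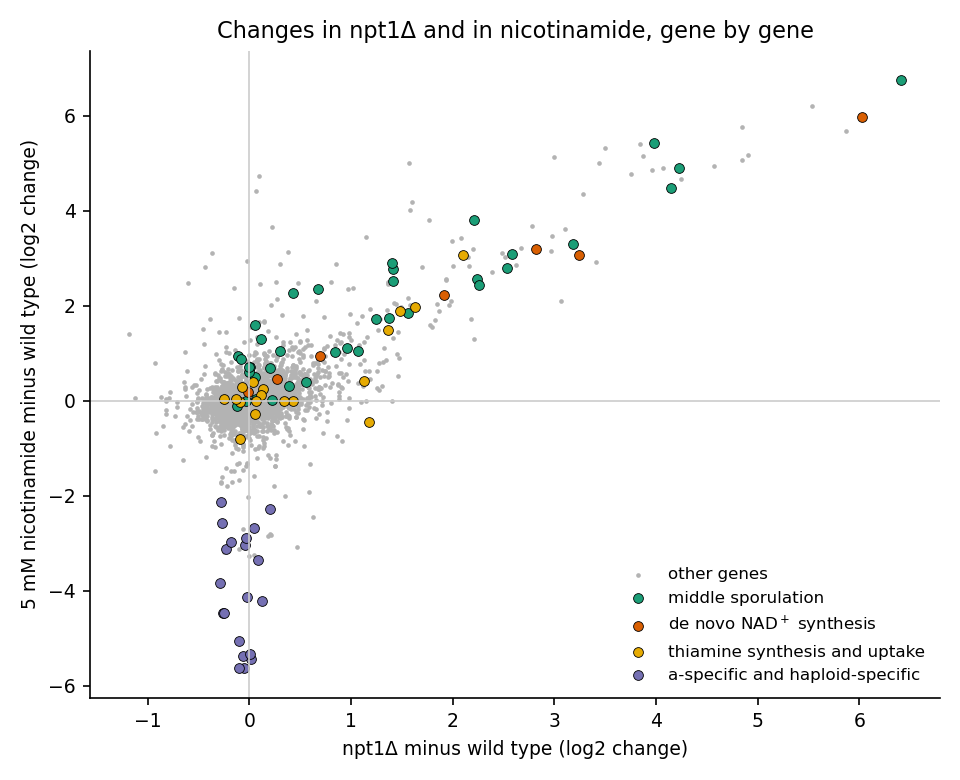
Log2 change of each gene in npt1Δ (horizontal axis) and in 5 mM nicotinamide (vertical axis), each against the 4 wild-type arrays, with NPT1 left out. Sporulation and de novo NAD+ genes extend along the diagonal, and the a-specific and haploid-specific genes lie near 0 in npt1Δ (mean -0.0851) and at a mean of -3.93 in nicotinamide.

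Genes near chromosome ends, where Sir2 represses transcription, were higher in npt1Δ and in nicotinamide. Among 235 measured genes within the 10 outermost of an end, 47 rose and 1 fell in npt1Δ (mean 0.34 log2), and 83 rose and 7 fell in nicotinamide (mean 0.51). Adjusted over the list alone these counts were 65 and 8, and 92 and 8. By camera the set was shifted up with adjusted p = 2.62e-14 and 4.93e-13 over the 5 comparisons, and with adjusted p = 0.00762 in both at an estimated correlation. For the 20 outermost genes the calls were lost with an estimated correlation (adjusted p = 0.0803 in both). After quantile normalization the means were 0.224 and 0.351. SEO1, a permease gene chosen after its values were seen, rose by 4.25 in npt1Δ and by 4.67 in nicotinamide. In pnc1Δ 7 rose and 6 fell, and none was called in bna1Δ or tna1Δ. Camera on the 235 genes gave adjusted p = 0.172, 0.116 and 0.763 in these strains. Against ML8 alone, camera placed the set down in bna1Δ and tna1Δ.

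**Figure D4:**
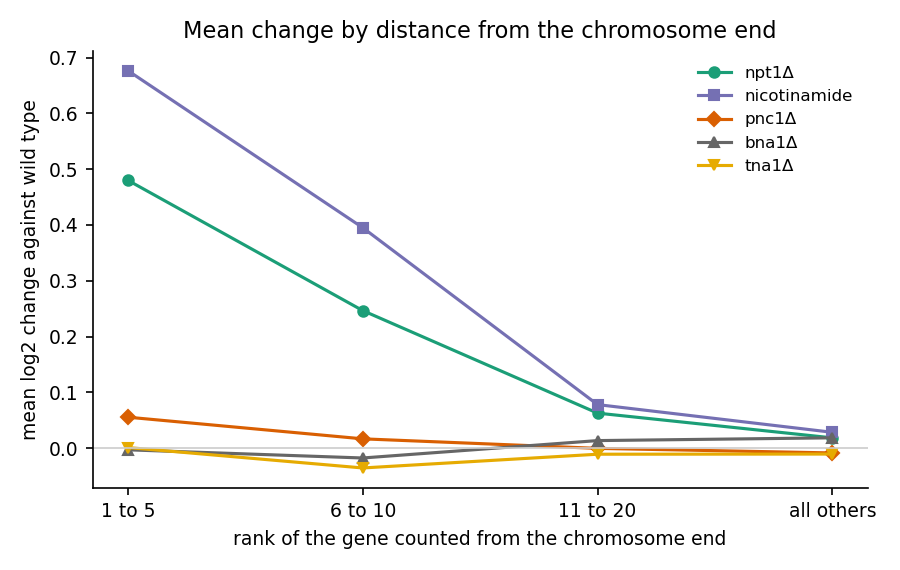
Mean log2 change against the 4 wild-type arrays of genes binned by rank from the chromosome end (horizontal axis), with 1 line per condition. For the 5 outermost genes the mean was 0.48 in npt1Δ and 0.68 in nicotinamide, and for genes of rank 11 to 20 it was 0.0627 and 0.078.

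Apart from PNC1 itself, the largest changes in pnc1Δ were the rise of SNO1 and the fall of YGP1. SNO1 and SNZ1, a pair of vitamin B6 genes, rose by 2.06 ± 0.17 (log2, 4.16-fold, adjusted p = 0.000258) and 1.22 ± 0.06 (adjusted p = 8.57e-06), the vacuolar transporter gene RTC2 by 1.45, the sulphate permease gene SUL1 by 1.43, the cyclin gene PCL5 by 1.17, SRY1 by 1.07, UGA3 by 1.03 and YKL183C-A by 0.94. The largest falls after PNC1 were those of YGP1, a secreted glycoprotein gene (-2.67 ± 0.20, 6.38-fold, adjusted p = 0.000119), YRO2 (-1.85), the hexokinase gene HXK1 (-1.73), STP4 (-1.54), the cytochrome oxidase gene COX5B (-1.48), RTC3 (-1.37) and the serine deaminase gene CHA1 (-1.30). In all, 123 of 5498 probe sets were called, 45 higher and 78 lower, with 7 and 12 at least 2-fold. This number fell to 22 without pnc1Δ array A, 51 without pnc1Δ array B and 71 without ML1 array B, and was 202 without ML1 array A. It was 190 against ML1 alone, 240 with the replicate letter as a block and 29 when only pnc1Δ and wild type were fitted.

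General amino acid control rose in pnc1Δ in 5 of 21 genes (14 adjusted over the list alone, adjusted p = 9.12e-12, and adjusted p = 0.0706 with an estimated correlation), with ARG4 at 0.93, SER3 at 0.53, LYS1 at 0.31 and HIS5 at 0.27 (log2). Tryptophan synthesis was shifted up by a mean of 0.18, with 0 of 9 called and 5 adjusted over the list alone (adjusted p = 7.27e-05, held with an estimated correlation), and TRP5 differed by 0.12. Environmental stress genes fell in 5 of 24 (11 adjusted over the list alone, adjusted p = 5.39e-11, and adjusted p = 0.0706 with an estimated correlation), among them the glutamate decarboxylase gene GAD1 at -0.93 and PGM2 at -0.71. The iron regulon was lower in 3 of 15, with FIT2 at -1.10, ARN2 at -0.89 and FIT3 at -0.81 (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.00301, and adjusted p = 0.149 with an estimated correlation). Purine synthesis was lower in 1 of 11, ADE17 at -0.40 (5 adjusted over the list alone, adjusted p = 3.37e-05, and adjusted p = 0.288 with an estimated correlation). The respiratory chain was lower in 5 of 29, with CYT1 at -0.93, QCR6 at -0.41, ATP3 at -0.38 and COX7 at -0.38 (8 adjusted over the list alone, adjusted p = 7.27e-05, and adjusted p = 0.384 with an estimated correlation). Against ML1 alone the respiratory chain was not shifted (adjusted p = 0.306). The de novo genes BNA5 and BNA6 fell by 0.79 and 0.38 without a shift of their list, and SUL1, QDR3 (0.66) and MHT1 (-0.55) were called in lists without a shift. Those lists were all the others tested, from the deleted genes to core histones (adjusted p from 0.067 to 0.941). With the replicate letter as a block, camera also called phosphate starvation and ribosome biogenesis.

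Loss of BNA1 or TNA1 in rich medium left a single called gene each against the 4 wild-type arrays, the deleted one, which was lower. Against ML8 alone 4 were called in bna1Δ and 6 in tna1Δ, against ML1 alone 2 in bna1Δ, and without tna1Δ array A 5 in tna1Δ. With the wild-type pairs as separate groups, YFR057W was lower in bna1Δ than in ML1 (adjusted p = 2.24e-08) and higher in tna1Δ than in ML8 (adjusted p = 3.02e-08), and SIR2 differed by 1.52 ± 0.19 between bna1Δ and ML1 (adjusted p = 0.024) and by -1.92 ± 0.19 between tna1Δ and ML8 (adjusted p = 0.00476). At an unadjusted p under 0.05 there were 172 probe sets in bna1Δ and 197 in tna1Δ, where chance alone gives 274.9. In bna1Δ the sulphur and methionine list was shifted down by a mean of -0.33 (log2) with 0 of 25 called (6 lower adjusted over the list alone, adjusted p = 1.4e-22), and the iron regulon by -0.30 with 0 of 15 called (2 lower adjusted over the list alone, adjusted p = 4.44e-19). Both held with an estimated correlation. FIT3 differed by -0.38 and CYS3 by 0.02, neither called. General amino acid control was placed down (mean -0.08, 0 of 21 by either count, adjusted p = 0.000716, adjusted p = 0.329 with an estimated correlation, and adjusted p = 0.546 against ML8 alone). The respiratory chain was placed up in bna1Δ (mean 0.13, 0 of 29, 1 adjusted over the list alone, adjusted p = 2.88e-06, adjusted p = 0.329 with an estimated correlation, and adjusted p = 0.933 against ML8 alone). It was also placed up in tna1Δ (mean 0.23, 0 of 29 by either count, adjusted p = 1.31e-07, and adjusted p = 0.498 with an estimated correlation). The list of deleted genes was placed down in both through the deleted gene itself, 1 of 4 by either count (adjusted p = 0.00817 in bna1Δ and 0.0005 in tna1Δ, and adjusted p = 0.101 and 0.0736 with an estimated correlation). This call was lost in bna1Δ against ML1 alone (adjusted p = 0.0691) or ML8 alone (adjusted p = 0.283), and in tna1Δ against ML1 alone (adjusted p = 0.166). The other lists were not shifted (adjusted p from 0.056 to 0.965 in bna1Δ and from 0.051 to 0.992 in tna1Δ). Without TNA1, NAD+ salvage was placed up in tna1Δ (adjusted p = 0.0489, and adjusted p = 0.513 with an estimated correlation). The iron regulon was placed down in tna1Δ against ML8 alone (adjusted p = 7.36e-05), and had adjusted p = 0.498 with an estimated correlation against all wild-type arrays.

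Conditions were also set against each other. Between bna1Δ and npt1Δ, the de novo and salvage mutants, 200 probe sets were called, 169 of them lower in bna1Δ. That number was 354 without ML1 array A, 117 without bna1Δ array A and 120 without bna1Δ array B. Between npt1Δ and pnc1Δ, mutants of the same salvage route, 331 were called, 262 of them higher in npt1Δ, and 183 were called without npt1Δ array B, 163 without pnc1Δ array A and 191 without pnc1Δ array B (169, 156 and 183 of them among the 331). Between nicotinamide and pnc1Δ, which lacks the nicotinamidase, 849 were called, 515 higher in nicotinamide, and 520 were called without pnc1Δ array A and 490 without nicotinamide array B (507 and 475 of them among the 849). Between bna1Δ and tna1Δ only BNA1 and TNA1 were called with the wild-type arrays as a single group, and 5 probe sets with the pairs separate. The single group counts the gap between ML1 and ML8 as error, which hides differences in genes that vary between the pairs. YFR057W was at 2.15 and 2.25 in bna1Δ against 6.64 and 6.54 in tna1Δ (log2). SIR2 was at 10.45 and 10.21 against 8.67 and 8.21. In npt1Δ SIR2 was at 10.4 and 10.2, near ML8, and in pnc1Δ at 9.11 and 8.67, near ML1. A gap like that between the pairs may therefore be among the 331 calls between these strains.

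Genes called in the same direction in at least 3 conditions changed in npt1Δ, pnc1Δ and nicotinamide. There were 13 higher and 3 lower, where 100 simulations with the changes of each condition at random genes gave 0.28 and 0.14 on average and at most 2 each. These simulations leave out wild-type arrays that stand apart, which can add shared calls. RTC2 rose by 1.33, 1.45 and 1.12 (log2) in npt1Δ, pnc1Δ and nicotinamide, YDR042C by 1.35, 0.69 and 1.90, and the proline oxidase gene PUT1 by 0.90, 0.76 and 1.23. SRY1, IMD2 (a shared probe set), the glucan synthase gene GSC2, SNZ1, HES1, the sulphite pump gene SSU1 and SER3 also rose, and GYP5, the arabinose dehydrogenase gene ARA1 and the alanine transaminase gene ALT1 fell. Of 45 genes higher in pnc1Δ, 14 were higher in npt1Δ (1.54 on average in these simulations and 4 at most) and 19 in nicotinamide (3.65 and 10). Of 78 lower in pnc1Δ, 6 were lower in npt1Δ (0.69 and 4) and 9 in nicotinamide (4.29 and 11), while 7 were higher in npt1Δ (2.45 and 8) and 21 in nicotinamide (5.8 and 13). Across all genes, which are not independent replicates, the changes in pnc1Δ correlated at 0.163 with those in npt1Δ and at 0.078 with those in nicotinamide, against 0.333 and 0.332 in simulations in which only the wild-type arrays link them. The covariances were 0.021 and 0.0142, above the simulated 0.00823 and 0.0082. When each condition had its own wild-type pair, the correlations were -0.0239 or 0.0201 and -0.0634 or 0.00602. Of the 13, 8 were left without npt1Δ array A or B, 2 without pnc1Δ array A and 4 without pnc1Δ array B. Of the 3, 0 were left without ML1 array B or either nicotinamide array, and 1 without ML8 array A or any npt1Δ, bna1Δ or tna1Δ array.

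Between the wild-type pairs ML1 and ML8 the test called 4 genes, among them the sirtuin gene SIR2. At an unadjusted p under 0.05 (limma) there were 988 probe sets, where chance alone gives 274.9. The same count against wild type was 850 in npt1Δ and 821 in pnc1Δ. YFR057W, a gene at a chromosome end, was at least 22.8-fold higher in ML1 (adjusted p = 4.31e-08), SIR2 differed by -1.55 ± 0.19 (log2), its neighbour PRP11 by -0.73 ± 0.09 and YER137C by 1.36 ± 0.16 (adjusted p = 0.0248 each, ML1 minus ML8). SIR2 signal was 8.96 and 8.65 in ML1, 10.35 and 10.36 in ML8, 10.4 and 10.2 in npt1Δ, 9.11 and 8.67 in pnc1Δ, 10.45 and 10.21 in bna1Δ, 8.67 and 8.21 in tna1Δ, and 9.65 and 9.69 with nicotinamide. YFR057W was below background in ML8 and bna1Δ and at least 6.14 on all other arrays. The number called was 1 without either bna1Δ array, either nicotinamide array or ML8 array A, and 2 without ML1 array A, ML8 array B or either pnc1Δ array. It was 1132 without ML1 array B, which leaves array A alone to stand for ML1. By camera, purine synthesis was placed up in ML1 (mean 0.18, adjusted p = 0.000485), and the respiratory chain (mean -0.28, adjusted p = 0.00212) and PAU genes (mean -0.21, adjusted p = 0.03) down, each at adjusted p = 0.673 with an estimated correlation.

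**Figure D5:**
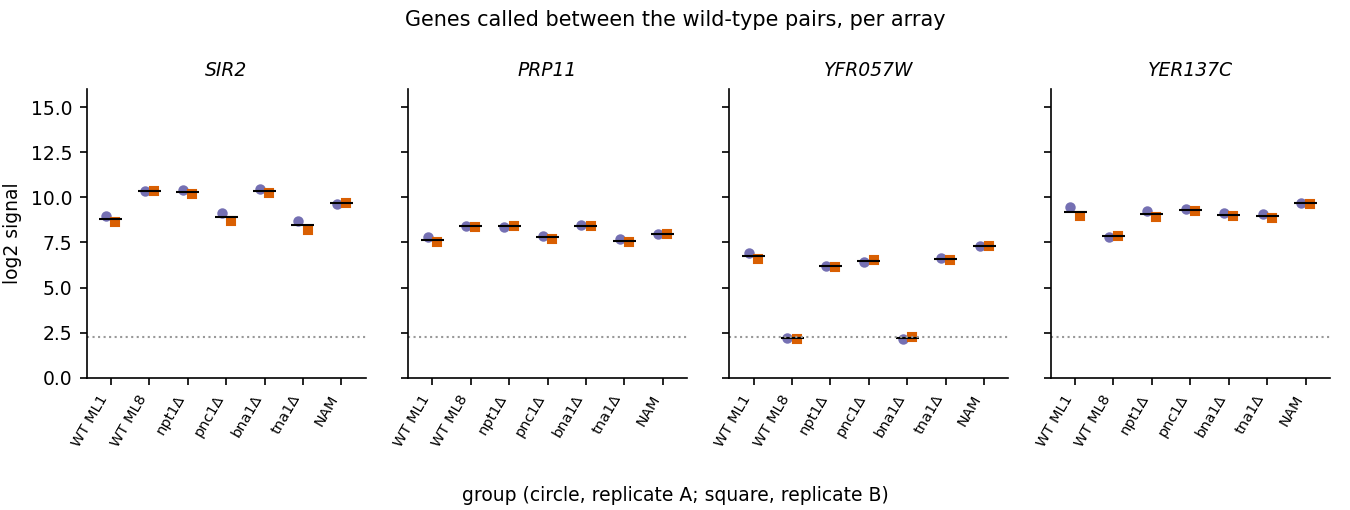
Log2 signal on each of the 14 arrays of the 4 genes called between the ML1 and ML8 wild-type pairs, with circles for replicate A, squares for replicate B, a bar for the mean of the pair, and a dotted line at the highest background limit, 2.26. SIR2 is between 8.21 and 9.11 in ML1, pnc1Δ and tna1Δ and between 10.2 and 10.45 in ML8, npt1Δ and bna1Δ.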

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

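The comparison of probe sets with no gene given was chosen only after the main results were seen, and the search for wild-type arrays that stand apart was planned. In the kanMX4 deletion strains 1 reporter control probe set of the array had a mean of 15.32 (log2) on the 8 arrays, with a range of 15.29 to 15.37, and a mean of 1.994 on the 6 arrays of wild type and nicotinamide, with a range of 1.94 to 2.023. The values separate the deletion strains from the strains without a deletion on every array, and the sequence that this probe set reads was not given in the sources used here. Among the 3470 probe sets with no gene given, which the comparisons of genes do not use, limma called 5 in npt1Δ (5 higher), 5 in pnc1Δ (1 higher and 4 lower) and 19 in nicotinamide (15 higher and 4 lower), and 0 in bna1Δ and in tna1Δ.

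A single wild-type array stood apart from the other 3 in 9 of 160 named probe sets, by Dixon's test of the gap to the next value. Chance marks about 1 in 20 groups, here about 8. ML1 array A was the highest for NPT1 at 12.54 (next value 12.36) and for CCM1 at 7.729 (7.285), and the lowest for NRT1 at 7.858 (8.091), for TRP5 at 14.25 (14.38) and for CYS3 at 14.25 (14.33). ML1 array B was the highest for HXK1 at 9.617 (9.053) and for OCH1 at 11.09 (10.95). ML8 array A was the lowest for SPR3 at 2.568 (2.821), and ML8 array B for BNA5 at 10.23 (10.46).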

How the results depend on the processing

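Lists without the deleted gene and the adjustment over 5 comparisons for genes near chromosome ends were chosen only after the result was seen, and the other alternatives here were planned. No called named gene changed direction under any of the alternatives run. Among lists that stayed called, NAD+ salvage in npt1Δ by fry changed direction (adjusted p = 2.52e-06, down). None did with an estimated correlation, with either control pair alone or without the deleted gene. The direction of lists with the block was not recorded, and the list tests were not rerun under the other alternatives. Some of the 177 named calls were lost when an array was left out, which leaves a lone array assumed to vary like the other groups. With only the groups compared 53 of the 177 were lost, with a 2-fold minimum 69, and under the other alternatives at most 26. That limit does not cover leaving out an array, which lost more in some cases, most of all without a pnc1Δ array. In npt1Δ 231 calls became 138 with only the groups compared and 112 with a 2-fold minimum. In pnc1Δ 123 became 190 against ML1 alone, 186 with the wild-type pairs separate, 240 with the replicate letter as a block, 29 with only the groups compared and 19 with a 2-fold minimum, and 22 to 202 with an array left out. In bna1Δ 1 became 2 against ML1, 4 against ML8, and 2 with the pairs separate, a variance trend, no moderation or all probe sets. In tna1Δ 1 became 6 against ML8, 2 with the pairs separate, and 1 to 5 with an array left out. In nicotinamide 874 became 533 with only the groups compared, 250 with a 2-fold minimum, and 458 to 1156 with an array left out. Between bna1Δ and npt1Δ 200 became 333 with only ML8 in the fit, 107 with a 2-fold minimum and 117 to 354 with an array left out. Between npt1Δ and pnc1Δ 331 became 191 with only these groups, 140 with a 2-fold minimum and 163 to 491 with an array left out. Between bna1Δ and tna1Δ 2 became 5 with only ML1, only ML8 or the pairs separate, and 2 to 5 with an array left out. Between nicotinamide and pnc1Δ 849 became 288 with a 2-fold minimum and 490 to 1195 with an array left out. Between ML1 and ML8, 4 became 1 with only these groups, no moderation or all probe sets, and 1 to 1132 with an array left out. Genes higher in at least 3 conditions, 13, became 22 against ML1 (7 of the 13 kept), 1 with only the groups compared or a 2-fold minimum, and 2 to 15 with an array left out. Genes lower in at least 3, 3, became 6 against ML1 or with the block, 0 with only the groups compared, median centring or a 2-fold minimum, and 0 to 3 with an array left out. Arrays with the same replicate letter deviated together from their group means (correlation above 0.1) in 17 of 21 pairs of groups, with a median of 0.387, and in opposite directions (below -0.1) in 2. Every pair of groups not above 0.1 included ML1, whose array A stood apart. Pairs of groups without ML1 lay between 0.107 and 0.593, so arrays of those groups share variation by letter. The planned main fit leaves the letter out, and the block was kept as an alternative. Of 37 list shifts 10 held with an estimated correlation. Over 115 tests of a list in a comparison, 6 calls were lost and 2 gained against ML1 alone, 4 lost and 15 gained against ML8 alone, and 6 lost and 8 gained by fry, which tests another question than camera. With the replicate letter as a block 2 were gained in pnc1Δ, phosphate starvation (adjusted p = 0.0289) and ribosome biogenesis (adjusted p = 0.0317). Their means in the main fit were -0.244 and 0.0629 (log2). Without the deleted gene 2 were gained in tna1Δ, NAD+ salvage and the iron regulon, the latter only because fewer lists were adjusted together. Against ML8 alone, camera placed genes near chromosome ends down in bna1Δ (adjusted p = 0.0135) and tna1Δ (adjusted p = 0.0243). Against ML1 alone the set had adjusted p = 0.0671 (up) in pnc1Δ, where the p before adjustment was under 0.05. Fits of fewer arrays have fewer degrees of freedom and a 2-fold minimum removes calls by construction. For the other changes the cause was not tested. After quantile normalization the share of calls that were higher went from 84.8% to 60.7% in npt1Δ and from 55.8% to 44.5% in nicotinamide. The filter on dim probe sets left out 61 of 5498. Signal over background limits the folds of genes such as NPT1 and YFR057W to lower bounds.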

Other observations

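The test of nicotinamide against npt1Δ, the bins by rank from the chromosome end, and all tests of explanations other than those on the region around SIR2 and on chromosome ends in ML1 were chosen only after the result was seen. Those on SIR2 and ML1 were set before their own values were seen, but after the genes called between ML1 and ML8 were known. Nicotinamide and the npt1 deletion, which shared 165 raised genes (of 488 and 196), differed in 497 of 5498 probe sets by limma, 291 higher and 206 lower in nicotinamide. Beyond the mating genes, sulphur and methionine genes were higher in nicotinamide than in npt1Δ in 15 of 25 (mean 0.58 log2, adjusted p = 2.1e-09), middle sporulation genes in 13 of 37 (mean 0.61, adjusted p = 6.43e-08) and iron regulon genes in 6 of 15 (mean 0.45, adjusted p = 0.000332), each at adjusted p = 0.062 with an estimated correlation. Phosphate starvation (mean 0.34, adjusted p = 0.0103, and adjusted p = 0.062 with an estimated correlation), ribosome biogenesis (mean 0.22, adjusted p = 0.00045, and adjusted p = 0.342) and genes near chromosome ends (40 higher and 11 lower, adjusted p = 0.0103, and adjusted p = 0.342) were also placed up. The respiratory chain (mean -0.26, adjusted p = 0.000396, and adjusted p = 0.372 with an estimated correlation) and core histones (mean -0.17, adjusted p = 0.00963, and adjusted p = 0.062) were placed down. The alpha-specific, thiamine, PAU and NAD+ lists did not pass this test (adjusted p from 0.0895 to 0.989), though 2 of 18 thiamine genes were higher and 4 lower, among them SNO3 (a shared probe set, chosen after its values were seen) at -1.62 (adjusted p = 0.00914).

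The 4 genes of daughter-cell separation given here were picked because their values in nicotinamide were high, so they say nothing of other such genes. DSE1 rose by 4.41 (adjusted p = 1.29e-09), DSE2 by 4.72 (adjusted p = 3.15e-07), the glucanase gene SCW11 by 3.10 (adjusted p = 2.83e-08) and the chitinase gene CTS1 by 2.95 (adjusted p = 2.58e-08), and in npt1Δ they differed by 0.07, 0.10, -0.37 and -0.02, none called. AMN1, an inhibitor of mitotic exit and of this separation programme, fell by 1.02 (adjusted p = 0.000244). IME4, a meiotic methyltransferase gene, rose by 2.81 and RME1, a repressor of entry into meiosis, fell by 2.27 in nicotinamide. AMN1, IME4 and RME1 were also chosen after their values were seen. Of the auxotrophic markers, HIS3 and MET17 were at background on all arrays, between 1.91 and 2.02, while LEU2 gave 14.04 to 14.3 and URA3 11.51 to 12.27.

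The fall of all 20 a-specific and haploid-specific genes in nicotinamide, by a mean of -3.93, was not seen in npt1Δ, at a mean of -0.0851, and the difference between these conditions passed the test for both lists (adjusted p = 5.45e-12 and 7.43e-23, and adjusted p = 0.0683 and 0.062 with an estimated correlation). The mean was -4.08 after a further quantile normalization and -3.89 after median centring. These values cannot weigh normalization as a cause, since the deposited values were already quantile normalized and array medians lay between 9.75 and 9.84. Cells of the opposite mating type are argued against, since they express the haploid-specific genes, which changed by a mean of -3.41. A candidate explanation is that both mating types were expressed after loss of silencing, as in a diploid, but HMLALPHA1 was above background on 0 arrays, so that its probe set cannot be shown to work, and no probe set was given for HMLALPHA2. It cannot be told apart here from a diploid culture, which was not tested and which a measure of DNA content would show.

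Without ML1 array A the differences of SIR2, PRP11 and YER137C between the ML1 and ML8 pairs were -1.71 ± 0.221, -0.845 ± 0.086 and 1.10 ± 0.14 (-1.55 ± 0.186, -0.727 ± 0.0892 and 1.36 ± 0.164 with it), and that of YFR057W, below background in ML8, was at least 4.33 (at least 4.51), which argues against the quality of that array. SIR2 and YER137C were then no longer called (adjusted p = 0.0747 each), with 1 array left for ML1, a larger error for SIR2 and a smaller difference for YER137C. A change in copy number of a larger region around SIR2 is argued against by the 10 measured genes nearest to SIR2 and PRP11, whose median difference was 0.0584 with a range of -0.942 to 0.214. A change in copy number of SIR2 and PRP11 alone could not be seen by this test, which leaves both out. A general loss of silencing at chromosome ends in ML1 is argued against by the mean of -0.0786 of the 234 other genes near the ends. A difference between the strains at the SIR2 locus may account for SIR2 and PRP11 and stays open, since the labels give both pairs 1 genotype, and sequencing of the locus in both strains would test it. It leaves YER137C unexplained, which was at 7.821 and 7.849 in ML8. That gene lay between 8.899 and 9.226 in npt1Δ and bna1Δ, where SIR2 was about as high as in ML8. At that level of SIR2 YFR057W was low in bna1Δ and high in npt1Δ, where other genes near chromosome ends rose as well. YFR057W was also high in ML1, pnc1Δ and tna1Δ, where SIR2 was lower, and in nicotinamide.

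The rise of genes near chromosome ends in npt1Δ and nicotinamide declined with distance from the end. The mean change in npt1Δ was 0.48 for genes 1 to 5, 0.25 for genes 6 to 10, 0.0627 for genes 11 to 20 and 0.02 for all others, and in nicotinamide 0.68, 0.40, 0.078 and 0.03. Probe sets shared between near-identical genes are argued against as the whole cause, since without PAU genes and shared probe sets the shift kept adjusted p = 0.00857 in npt1Δ and in nicotinamide with an estimated correlation. The decline is in line with reduced silencing by Sir2 from the ends inward, a hypothesis that these arrays alone leave open and that arrays of a strain without SIR2, with and without nicotinamide, would test. Other sirtuins, which were not told apart by any strain here, may contribute. A lower SIR2 transcript did not go with such a rise. In pnc1Δ and tna1Δ, where SIR2 signal lay between 8.21 and 9.11, genes near the ends averaged 0.03 and -0.02 against wild type. In ML1, at a similar SIR2 signal, they averaged -0.0786 against ML8, with YFR057W left out. These values concern the transcript, and the activity of Sir2 was not measured.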
